A study of Mus musculus with 24 samples.

How the data were processed

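RNA from 8 mouse cell types, with 3 samples of each, was measured on Affymetrix GeneChip Mouse Gene 1.0 ST arrays, which carry probes along the exons of each gene. Per the labels' protocols, RNA was extracted with the miRNeasy mini kit, and 200 ng of total RNA from each sample was labelled with biotin. The deposited table holds 1 value for each of 35556 probesets in each of the 24 arrays, on a log2 scale, and the submitters' processing notes name RMA (robust multi-array average) and the Partek software. In its usual form RMA corrects the background, brings the arrays to a common distribution and summarises the probes of a probeset. The base of the logarithm was inferred from the values, which ran from 3.14 to 14.43 over all arrays. The chip definition, the level at which probes were summarised and any filter on probesets were not given in the sources used here.

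Samples were grouped by the cell type in their labels, and every deposited column was used. Per the labels, iPSC, iPS-MG, neo-MG and ad-MG carried the fluorescent protein gene gfp in place of 1 copy of Cx3cr1 in the C57BL/6NCr strain. DC, NSC, bm-Mac and p-Mac came from C57BL/6NCr without it, so that strain and cell type could not be separated between the microglial and the other myeloid samples. Per the labels' protocols, iPSC grew with leukaemia inhibitory factor on inactivated mouse embryonic fibroblasts. Cells named gMG there, a name the labels do not define, received GM-CSF, M-CSF and IL-3 at 20 ng/mL each, and all other cells were kept in DMEM/F12 medium with defined serum. Nothing in the labels says whether the 3 samples of a group came from separate animals or cultures. The p-values therefore measure only the spread between these samples, which may be technical.

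Median values over all probesets were 8.06, 8.05 and 8.05 in iPSC replicates 1 to 3, 7.98, 7.97 and 7.98 in iPS-MG, and 7.99, 8.00 and 7.98 in neo-MG. They were 8.06, 8.07 and 8.02 in ad-MG, 7.96, 7.97 and 7.97 in DC, and 8.04, 8.04 and 8.00 in NSC. In bm-Mac they were 8.07, 8.09 and 8.11, and in p-Mac 8.17, 8.21 and 8.21. No scanner values or detection calls were used here, so the number of arrays limits the precision and no level could be called absent.

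Probesets were named from the platform annotation, which can be old. Of the probesets, 21218 carried 1 gene symbol, 1881 carried several and 12457 carried none. Probesets with several symbols or none were left out. Among the single-gene probesets, 21185 were found by Entrez ID in a RefSeq gene table, and 0 symbols needed an update. For the 1386 genes with more than 1 probeset, the probeset with the highest mean over all arrays was kept, which left 18820 genes. No genome was used and no coordinates are given.

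Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) on the deposited log2 values, with Benjamini-Hochberg adjustment over the 18820 genes. A gene was called different at an adjusted p under 0.05 and an absolute log2 difference of at least 1, which is 2-fold. The 8 comparisons of 2 cell types came from 1 fit to all 24 arrays, which shares the estimate of the spread. The comparison of primary microglia (neo-MG and ad-MG) with other myeloid cells (bm-Mac, p-Mac and DC) came from a fit to those 15 arrays. The standard error of a log2 difference is written after ± beside a difference, and the SD over the arrays of a group is written after ± beside a level. The position of iPS-MG between other myeloid cells (0) and primary microglia (1) was the median, over genes called in that fit without overlap of the arrays, of the distance from the myeloid mean divided by the distance between both means. Similarity was Pearson's r across genes, and genes are not independent replicates. These choices, the gene lists and the rule for named genes were made before the data were examined.

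The rule named, in each main comparison, the 8 protein-coding genes with the highest and the 8 with the lowest log2 difference among called genes whose arrays did not overlap. In the comparisons with p-Mac, DC and NSC it named 3 each way. It also named the 2 highest and 2 lowest members of each list described, and a fixed set of identity genes: Cx3cr1, P2ry12, Tmem119, Sall1, Csf1r, Itgam, Ptprc, Aif1, Spi1, Pou5f1, Nanog, Nes, H2-Aa, Cd74, Trem2, Apoe, Arg1, Xist and the Y chromosome genes Eif2s3y, Kdm5d and Uty. Genes named outside the rule are said to have been chosen after their values were seen. Some members of the lists, and some that the fixed set held beside the genes printed here, were not analysed here.

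The 31 gene lists held markers and processes. The cell type lists were microglia-enriched, pan-myeloid, peritoneal macrophage, monocyte and bone marrow lineage, dendritic cell, pluripotency, neural progenitor, neuron, astrocyte, oligodendrocyte lineage, endothelium and mural cell, fibroblast, B cell, T and NK cell, mast cell and basophil, granulocyte, erythroid and haematopoietic progenitor. The others were complement and phagocytic receptors, MHC class II presentation, cytokines and chemokines, alternative activation, interferon response, STAT5 targets and growth factor receptors, cell cycle, lipid-associated activated microglia, cholesterol synthesis, glycolysis and hypoxia, immediate early and stress, purinergic receptors, and sex-linked transcripts. Some genes stood on more than 1 list, and the lists describe the RNA of whole samples. Each list was tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the lists of a comparison. Camera was run again with an estimated correlation, and fry, which tests whether the genes of a list move on balance 1 way, was run beside it. Of the 279 list tests, 126 passed with the preset correlation, 73 of these also passed with an estimated correlation, and 53 did not. A list's median, mean and camera direction differed in sign in 59 tests, 0 of which passed the camera test.

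The scripts were tested on simulated data in which 200 of the 18820 genes were changed by known amounts. True log2 differences of 1.5 and 3 were called for 100% of genes in all 9 comparisons. True differences of 0.5 lay under the minimum and were called for 0%, although 82.1% to 100% of them reached an adjusted p under 0.05. At most 1 unchanged gene per comparison was called, 2 of 279 unchanged lists passed camera, and a simulated position of 0.7 was recovered as 0.703. The simulated noise was independent between genes, so the list result does not cover correlation between genes, on which list calls depended in the real data. The position was simulated by the formula that recovers it, so its recovery checks the code alone. The alternatives tried were other sets of arrays in the fit, the replicate number as a block, centring of each array on its median, a second quantile normalization, a filter on dim genes, the mean of a gene's probesets, an intensity trend, array weights, no fold minimum and each replicate left out in turn. For the position and the similarity they also included other genes, averages and reference groups.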

Results

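The 24 arrays set microglia-like cells grown from mouse induced pluripotent stem cells beside the stem cells and beside 6 kinds of primary cells. iPSC were the stem cells and iPS-MG, by their name, GFP-positive cells derived from such stem cells, called the derived cells below. Whether they came from the line on the iPSC arrays stays open, given the sex-linked transcripts described below. The primary cells were microglia of postnatal day 5 (neo-MG) and of adult mice (ad-MG), dendritic cells (DC), bone marrow macrophages (bm-Mac), peritoneal macrophages (p-Mac) and neural stem cells of embryonic days 15 to 18 (NSC). Each group held 3 arrays. Within groups, Pearson's r across genes lay between 0.9952 and 0.9986, and the root mean square log2 difference between 0.113 and 0.204.

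Neonatal microglia were the nearest group to iPS-MG. The 3 iPS-MG arrays had a mean r of 0.9983 across 18820 genes with the neo-MG mean and a root mean square log2 difference of 0.123 ± 0.010 (SD, n = 3). Between single arrays the difference averaged 0.141 (0.128 to 0.164) from iPS-MG to neo-MG, 0.132 within iPS-MG and 0.121 within neo-MG. The distance was 0.537 ± 0.012 to bm-Mac (r = 0.9666), 0.542 ± 0.0073 to ad-MG (r = 0.966), 0.679 ± 0.0087 to p-Mac (r = 0.9454) and 0.68 ± 0.0037 to DC (r = 0.9465). It was 1.14 ± 0.0035 to NSC (r = 0.8451) and 1.15 ± 0.0014 to iPSC (r = 0.8463). For 23 of the 24 arrays the nearest other array belonged to the same group. The exception was iPS-MG replicate 2, which lay 0.132 from neo-MG replicate 1 and 0.136 from the nearest iPS-MG array. Genes are not independent replicates, and 3 arrays allow no exact test below 0.05, so these distances are descriptive. In what follows, a gene that did not pass missed the adjusted p of 0.05 or the 2-fold minimum, and differences are in log2 units.

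**Figure D1:**
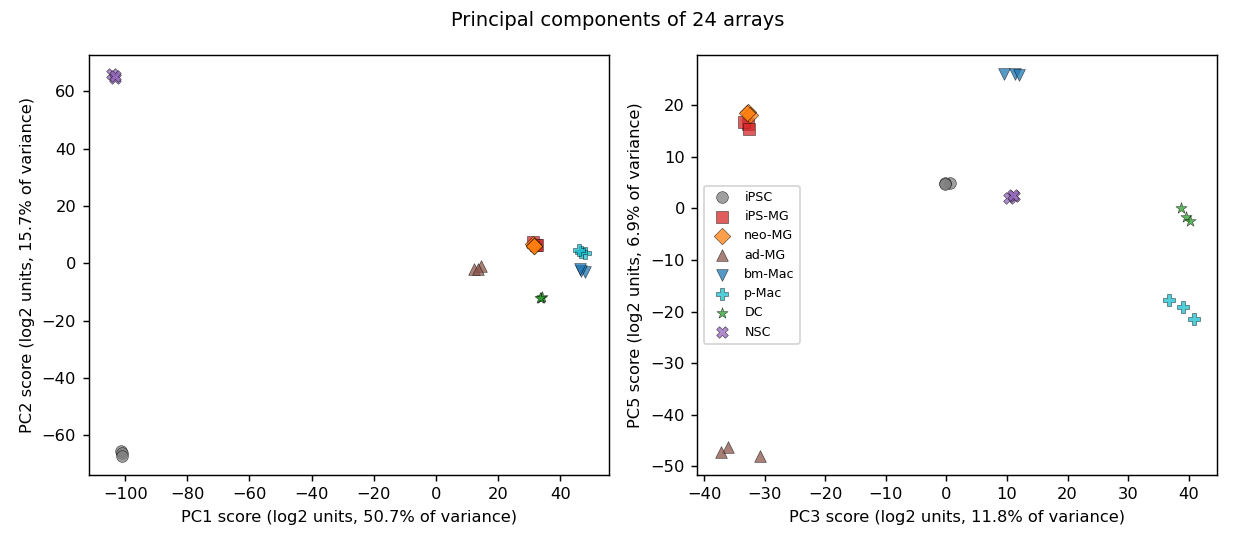
Principal components of the 24 arrays over 18820 genes, with 1 point per array coloured by cell type: component 1 (50.7% of the variance) against component 2 (15.7%) on the left and component 3 (11.8%) against component 5 (6.9%) on the right, axes in log2 units. The 3 iPS-MG points lie beside the neo-MG points in both panels, while ad-MG and each macrophage or dendritic cell group form separate clusters.

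iPS-MG were compared with iPSC to see what the derived cells gained and lost. Tlr7, an endosomal receptor for single-stranded RNA, was 148-fold higher in iPS-MG, with a log2 level of 12.79 ± 0.042 against 5.58 ± 0.14 in iPSC (SD, n = 3 each; log2 difference 7.21 ± 0.11, limma with Benjamini-Hochberg adjusted p = 1.05e-26). Cd5l, a secreted macrophage protein, rose by 7.20 ± 0.11, Cd36, a scavenger receptor that binds lipids, by 7.10 ± 0.11, and Atp6v0d2, a subunit of the vacuolar proton pump, by 7.02 ± 0.094. Ly86, which pairs with a Toll-like receptor homologue, rose by 6.79, and the leukocyte receptors Cd84, Clec4a1 and C3ar1, the last for complement fragment C3a, rose by 6.75, 6.68 and 6.58.

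Stem cell genes went the other way. Nanog, a core transcription factor of pluripotency, was 75.6-fold lower in iPS-MG (6.88 ± 0.012 against 13.12 ± 0.078, n = 3 each; log2 difference -6.24 ± 0.062, limma with Benjamini-Hochberg adjusted p = 9.55e-30). Tdgf1, a co-receptor for Nodal, fell by 6.48 ± 0.095, and Pou5f1, which encodes Oct4, fell by 5.60 ± 0.12. Differences were -6.35 for Dppa5a, -6.35 for Zfp979, -6.26 for the nuclear receptor gene Nr0b1, -5.88 for Utf1, -5.80 for Epp13 and -5.80 for Fbxo15.

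Genes of myeloid identity rose as a group. Csf1r, the receptor for M-CSF, rose by 5.40 ± 0.080, Ptprc, the pan-leukocyte phosphatase CD45, by 5.46 ± 0.083, Spi1, the myeloid transcription factor PU.1, by 5.03 ± 0.12, and Itgam, the integrin CD11b, by 4.98 ± 0.098. All 29 measured pan-myeloid genes rose, with a median log2 difference of 4.68 (limma camera, Benjamini-Hochberg adjusted p = 6.24e-21). Adgre1 and Cd53 rose most, by 6.47 and 6.17, and Laptm5 and Csf2ra least, by 1.27 and 1.24. Of 29 microglia-enriched genes, 15 rose, 2 fell and 12 did not pass (camera adjusted p = 2.77e-07, limma with Benjamini-Hochberg). Entpd1, an ectoenzyme that cleaves ATP, and Fcrls rose by 6.46 and 6.38, while Golm1 fell by 1.41 and Sparc, a matrix protein, fell by 1.98. The ADP receptor P2ry12 rose by 3.64 ± 0.13, the lipid receptor Trem2 by 4.54 ± 0.062, Aif1, which encodes Iba1, by 3.87 ± 0.15, and the fractalkine receptor Cx3cr1, of which both groups carry only 1 intact copy, by 2.05 ± 0.068. Tmem119 and the transcription factor gene Sall1 did not pass, with differences of 0.82 ± 0.086 and 0.05 ± 0.12, nor did Apoe at 0.40 ± 0.061 and H2-Aa at 0.59 ± 0.092.

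Immune process lists rose too. In the list of complement and phagocytic receptors 21 of 26 genes rose and 1 fell, and in the interferon response 26 of 28 rose, led by Trim30a (5.30) and Rsad2 (4.50), with Bst2 at 0.77 and Ddx58 at 0.49 not passing (limma camera, Benjamini-Hochberg adjusted p = 5.65e-13 and 5.17e-15). Among cytokines and chemokines 20 of 31 rose, with Ccl3 at 5.97 and Il1a at 5.61, and 2 fell, Il23a at -1.37 and Ptgs2 at -1.41. Of the lipid-associated activated microglia genes 13 of 17 rose, with Clec7a at 6.15 and Lpl at 5.46, of purinergic receptors 8 of 10 rose and Nt5e fell, and of the monocyte and bone marrow lineage 10 of 17 rose and 3 fell. These lists had camera adjusted p-values of 3.78e-08, 1.63e-10, 1.46e-05 and 0.00969 in that order (limma with Benjamini-Hochberg). The pluripotency list fell in 25 of 26 genes (median -4.36, limma camera with Benjamini-Hochberg adjusted p = 7.62e-17), with Klf2 at -0.74 not passing.

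Some list calls depended on the correlation assumed between genes. Cell cycle genes fell in 22 of 27 cases, from -2.40 for Cdc20 and -2.78 for Cenpf to values that did not pass, -0.68 for Kif23 and 0.40 for Pcna (limma camera with Benjamini-Hochberg adjusted p = 3.64e-10 with the preset and adjusted p = 0.116 with an estimated correlation). Cholesterol synthesis genes rose in 9 of 16 cases, alternative activation genes rose in 5 and fell in 2 of 14, immediate early and stress genes rose in 7 and fell in 1 of 19, and fibroblast genes fell in 3 of 16, with Fbln1 at -2.04 and Prrx1 at -1.57, where iPSC had been kept on feeder fibroblasts. The alternative activation list held Mrc1, a mannose receptor, at 6.25 and Cdh1, the adhesion molecule E-cadherin, at -4.84. For these lists the adjusted p with an estimated correlation was 0.22, 0.0638, 0.466 and 0.282 (limma camera with Benjamini-Hochberg). The alternative activation and immediate early calls also ended after centring each array on its median (adjusted p = 0.0712 for both, limma camera with Benjamini-Hochberg). After a second quantile normalization the adjusted p was 0.0605 and 0.0641 for these and 0.0733 for fibroblast genes (limma camera with Benjamini-Hochberg). The count of every list named for this comparison was the same adjusted over the list alone.

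Transcripts tied to sex chromosomes also differed between iPS-MG and iPSC. Xist, the RNA that silences an X chromosome in female cells, rose by 2.97 ± 0.059 log2 units to 12.15 ± 0.054 (n = 3 each; limma with Benjamini-Hochberg adjusted p = 3.15e-24). The Y chromosome genes Eif2s3y, Kdm5d and Uty rose as well, by 3.18 ± 0.099, 2.28 ± 0.13 and 1.53 ± 0.081, so that all 4 measured sex-linked transcripts were higher in the derived cells, as were 4 adjusted over the list alone (limma camera with Benjamini-Hochberg adjusted p = 0.0013).

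In all, 4177 of 18820 genes (22.2%) were called, 1961 higher and 2216 lower in iPS-MG. Centring each array on its median shifted the median difference of all genes by 0.105, from 0.02 to 0.12, and left 2181 genes higher and 1949 lower, so that the direction with more genes depended on the scaling.

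**Figure D2:**
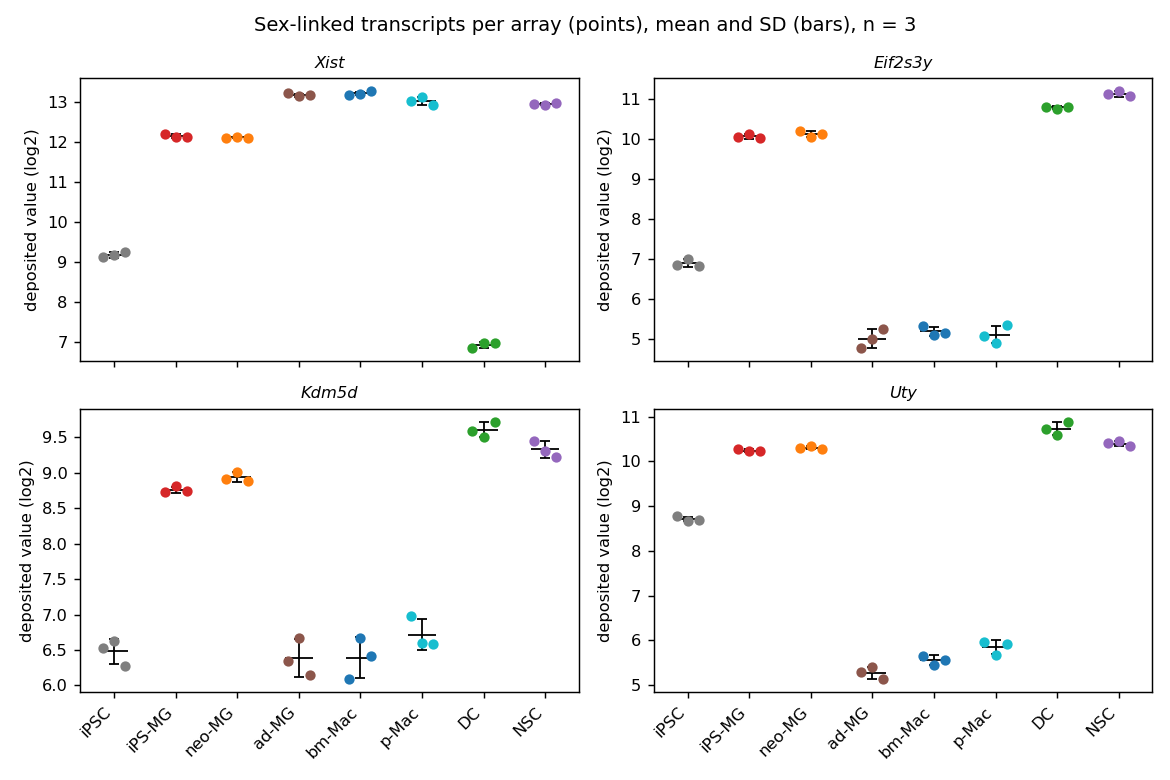
Log2 levels of Xist and of the Y chromosome genes Eif2s3y, Kdm5d and Uty in each array (points), with the group mean and SD (line and bar, n = 3) for the 8 cell types along the horizontal axis. iPS-MG and neo-MG share intermediate levels of all 4 transcripts (Xist 12.15 ± 0.054 and 12.12 ± 0.014), whereas iPSC lie at 9.18 ± 0.065 for Xist.

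The comparison of iPS-MG with neo-MG asked how closely the iPS-MG arrays matched microglia of newborn brain. Whether mixed-sex cells like neo-MG gave most of the iPS-MG RNA stays open, as set out further on, which limits what a match means. Only 5 of 18820 genes were called, all higher in iPS-MG. Ccn3, a matricellular protein, was 4.13-fold higher (9.67 ± 0.12 against 7.63 ± 0.14, n = 3 each; log2 difference 2.04 ± 0.15, limma with Benjamini-Hochberg adjusted p = 1.77e-09). Timp3, an inhibitor of metalloproteinases, was higher by 1.77 ± 0.066, the carbonic anhydrase gene Car6 by 1.36 ± 0.11, the arginase gene Arg1 by 1.26 ± 0.075 and fibronectin, Fn1, by 1.14 ± 0.053. Genes of microglial identity did not pass, and their values were close. Differences were 0.00 ± 0.13 for P2ry12, 0.20 ± 0.068 for Cx3cr1, 0.07 ± 0.086 for Tmem119, 0.06 ± 0.12 for Sall1, 0.00 ± 0.080 for Csf1r and -0.03 ± 0.062 for Trem2. Xist differed by 0.03 ± 0.059, Eif2s3y by -0.06 ± 0.099, Kdm5d by -0.18 ± 0.13 and Uty by -0.06 ± 0.081.

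At an adjusted p under 0.05 without the 2-fold minimum, 40 genes differed, all higher in iPS-MG, the 5 called genes included. The count of genes lower in iPS-MG was 0 by limma with Benjamini-Hochberg at either setting. In either direction 1225 of 18820 genes had an unadjusted p under 0.05, and chance alone would give most of that count at this threshold. In data simulated for this comparison, 100% of 67 genes with a true difference of 1.5 were called.

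Lists shifted little between iPS-MG and neo-MG. In the monocyte and bone marrow lineage list Fn1 rose and the other 16 of 17 genes did not pass, with Chil3 at 0.91 next and Hp lowest at -0.12 (limma camera with Benjamini-Hochberg adjusted p = 1.65e-14, and 3.28e-05 with an estimated correlation). In the alternative activation list Arg1 rose and 13 of 14 did not pass (limma camera with Benjamini-Hochberg adjusted p = 6.59e-06, and 0.000955 with an estimated correlation). The remaining shifts held only with the preset correlation. They were those of the pan-myeloid, MHC class II presentation, peritoneal macrophage and cytokine lists, whose adjusted p with an estimated correlation was 0.0829, 0.0802, 0.0757 and 0.0802 (limma camera with Benjamini-Hochberg), and whose medians were 0.04, 0.12, 0.01 and 0.10. Among the STAT5 targets Socs2, a feedback inhibitor of cytokine signalling, lay at 0.61, among lipid-associated genes Csf1, which encodes M-CSF, at 0.72, and among hypoxia genes Egln3, a prolyl hydroxylase induced by low oxygen, at 0.63. For these lists the adjusted p with an estimated correlation was 0.0802, 0.0802 and 0.0802, and it was 0.214 for immediate early and stress genes (limma camera with Benjamini-Hochberg). The pan-myeloid and lipid-associated calls also ended after a second quantile normalization (adjusted p = 0.278 and 0.175, limma camera with Benjamini-Hochberg), which turned the median of the latter from 0.03 to -0.005. The microglia-enriched list did not pass, with 0 of 29 genes called by limma, 2 at an unadjusted p under 0.05 and a median of 0.01 (limma camera with Benjamini-Hochberg adjusted p = 0.251). Adjusted over the list alone, 1 gene each was called in the monocyte, alternative activation and peritoneal macrophage lists, as over all genes.

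**Figure D3:**
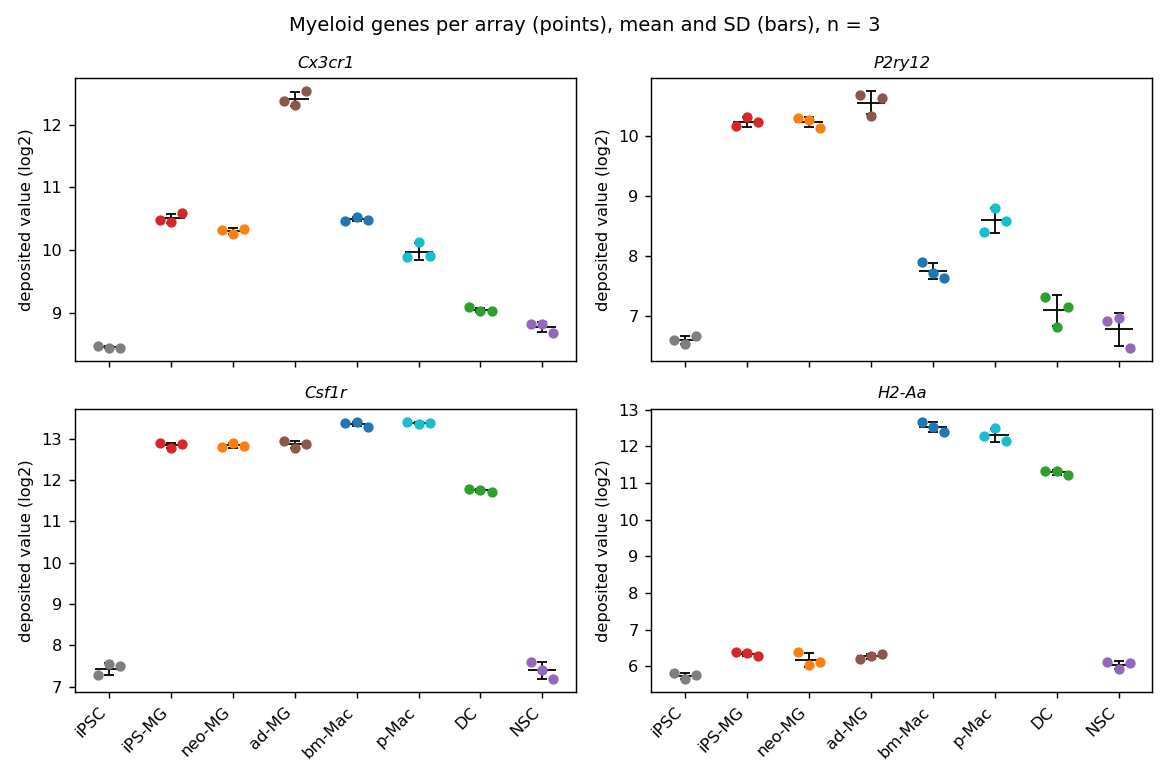
Log2 levels of Cx3cr1, P2ry12, Csf1r and H2-Aa in each array (points), with group mean and SD (line and bar, n = 3), for the 8 cell types along the horizontal axis. Cx3cr1 is highest in ad-MG at 12.41 ± 0.11, P2ry12 is alike in iPS-MG (10.24 ± 0.082) and neo-MG (10.23 ± 0.084), and H2-Aa is at 12.53 ± 0.13 in bm-Mac, 12.31 ± 0.18 in p-Mac and 11.29 ± 0.065 in DC.

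iPS-MG were next compared with microglia of adult mice. Sex-linked transcripts differed between these groups, so sex cannot be separated from age or origin of the cells here. The Y chromosome genes Eif2s3y and Uty were 33.5-fold and 31.4-fold higher in iPS-MG (log2 difference 5.07 ± 0.099 and 4.97 ± 0.081, n = 3 each; limma with Benjamini-Hochberg adjusted p = 5.15e-23 and 3.93e-24), and Xist was lower by a log2 difference of -1.03 ± 0.059. Cd36 was higher by 4.09 ± 0.11, Il12rb2, a subunit of the interleukin-12 receptor, by 3.19 ± 0.094, and Mcoln3, a lysosomal cation channel, by 3.16 ± 0.087. Cmbl, Mamdc2 and Slc24a5 were higher by 3.58, 3.14 and 3.00. Prl, the pituitary hormone prolactin, fell by 5.13 ± 0.12, with 11.11 ± 0.32 in ad-MG. Collagen XII (Col12a1) fell by 4.58 ± 0.067, and differences were -4.50 for the natriuretic peptide receptor Npr3, -4.36 and -4.36 for the matrix proteoglycans Fmod and Ogn, -4.09 for the growth factor Bmp4, -4.08 for Ccdc80 and -4.02 for Plod2, which modifies collagen.

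Adult microglia carried more Cx3cr1 and Tmem119. iPS-MG were lower by 3.74-fold for Cx3cr1 (log2 difference -1.90 ± 0.068) and 3.05-fold for Tmem119 (-1.61 ± 0.086), whereas P2ry12 (-0.32 ± 0.13) and Csf1r (-0.03 ± 0.080) did not pass. Of 29 microglia-enriched genes 7 fell and 22 did not pass, with Sparc at -2.71 and Sall1 highest at 0.66 without passing (limma camera with Benjamini-Hochberg adjusted p = 0.000149, and adjusted p = 0.102 with an estimated correlation). Fibroblast genes were lower in iPS-MG in 13 of 16 cases with a median of -2.29, among them Lum (-3.35) and Dcn (-3.10), while Fap (-0.20) and Col5a1 (0.07) did not pass (limma camera with Benjamini-Hochberg adjusted p = 4.03e-17). Endothelial and mural genes were lower in 4 of 13 cases, with Pdgfrb at -3.02 and Cdh5 at -2.64 (limma camera with Benjamini-Hochberg adjusted p = 1.55e-05, and adjusted p = 0.0954 with an estimated correlation).

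Interferon response genes were higher in iPS-MG than in ad-MG in 12 of 28 cases, with Irf7 at 2.29 and Rsad2 at 2.17 (limma camera with Benjamini-Hochberg adjusted p = 5.82e-17). Glycolysis and hypoxia genes were lower in 6 of 17 cases, with Egln3 at -2.55 and Adm at -2.47, and MHC class II presentation genes in 4 of 11, with H2-Ob at -2.21 and H2-DMa at -2.10 (limma camera with Benjamini-Hochberg adjusted p = 6.74e-13 and 7.59e-05). Immediate early and stress genes, which respond to handling, were lower in 6 of 19 cases, with Nr4a1 at -1.41 and Btg2 at -1.28, and peritoneal macrophage genes were lower in 6 and higher in 1 of 21, with a median that turned from -0.07 to 0.08 after centring. With an estimated correlation these lists had adjusted p = 0.0954 and 0.0524, the cell cycle list, with 2 of 27 genes higher, adjusted p = 0.192, and cholesterol synthesis, with 1 of 16 higher, adjusted p = 0.124 (limma camera with Benjamini-Hochberg). The counts against ad-MG were the same adjusted over the list alone.

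Of 1031 genes called against ad-MG, 226 were higher and 805 lower in iPS-MG, but without the 2-fold minimum 4094 were higher and 3863 lower. Centring shifted the median of all genes by 0.157 and gave 351 higher and 682 lower genes, moving the share of higher genes from 21.9% to 34%, and after it Xist no longer passed, at a log2 difference of -0.87. The fibroblast list had a median of -2.13 after centring, and the sex-linked list then ended its call (adjusted p = 0.0554 against 0.00492, limma camera with Benjamini-Hochberg).

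neo-MG were compared with ad-MG to show how microglia of both ages differed without the derived cells. This comparison shares the ad-MG arrays with the one above, so that both sets of values are not independent. Because sex-linked transcripts differed here as well, age and sex cannot be separated. Prl was 33.2-fold lower in neo-MG (log2 difference -5.05 ± 0.12, n = 3 each; limma with Benjamini-Hochberg adjusted p = 9.02e-22). Also lower were Ogn at -4.78, Col12a1 at -4.52, Fmod at -4.32, Ccdc80 at -4.23 and Plod2 at -4.20, as were Npr3 at -4.41 and Bmp4 at -4.24. Higher in neo-MG were Eif2s3y and Uty (5.12 ± 0.099 and 5.04 ± 0.081), Cd36 (4.07 ± 0.11), Cmbl (3.51), Il12rb2 (3.22), Mamdc2 (3.17), Mcoln3 (3.12) and Slc24a5 (2.99), the last an ion exchanger known from pigment cells. Cx3cr1 and Tmem119 were 4.29-fold and 3.20-fold lower (-2.10 ± 0.068 and -1.68 ± 0.086).

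Fibroblast genes were lower in neo-MG than in ad-MG in 13 of 16 cases (median -2.36), with Lum at -3.42 and Pdgfrb at -3.19 lowest (limma camera with Benjamini-Hochberg adjusted p = 2.14e-16). The fibroblast list averaged 10.18 ± 0.069 log2 units in ad-MG (SD, n = 3) and 8.16 ± 0.017 in neo-MG. Interferon response genes were higher in 13 of 28 cases, with Irf7 at 2.27 and Ifit2 at 2.15, and lower genes included 8 of 17 of glycolysis and hypoxia (Egln3 -3.18, Vegfa -2.56), 4 of 11 of MHC class II presentation (H2-DMa -2.41) and 6 of 21 of the peritoneal macrophage list, where Vsig4 was higher by 1.97 and the median turned from -0.09 to 0.05 after centring. Their adjusted p-values were 3.03e-16, 7.46e-14, 1.13e-05 and 0.00171 in that order (limma camera with Benjamini-Hochberg). Calls that were lost with an estimated correlation were those of immediate early and stress genes (8 of 19 lower, adjusted p = 0.0696), microglia-enriched genes (7 of 29 lower, adjusted p = 0.0929), endothelial and mural genes (4 of 13 lower, adjusted p = 0.0929), the cell cycle (2 of 27 higher, adjusted p = 0.182), cholesterol synthesis (1 of 16 higher, adjusted p = 0.13) and neural progenitors (1 of 21 higher and 4 lower, adjusted p = 0.341), all by limma camera with Benjamini-Hochberg. The neural progenitor call also ended after a second quantile normalization (adjusted p = 0.078, limma camera with Benjamini-Hochberg). None of these counts changed when adjusted over the list alone.

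Of 1075 genes called between neo-MG and ad-MG, 241 were higher and 834 lower in neo-MG, against 4586 higher and 3752 lower without the 2-fold minimum. Centring shifted the median of all genes by 0.147 and gave 346 higher and 724 lower genes, and after it Xist no longer passed, at -0.91, nor did the sex-linked list (adjusted p = 0.0611, limma camera with Benjamini-Hochberg).

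Against bone marrow macrophages, the comparison separated iPS-MG from macrophages of adult haematopoiesis. The highest differences in iPS-MG were those of the Y chromosome genes Eif2s3y and Uty (4.88 ± 0.099 and 4.69 ± 0.081 log2 units, n = 3 each; limma with Benjamini-Hochberg adjusted p = 6.72e-23 and 2.95e-24). Adamts1, a secreted protease, was 10.2-fold higher (3.35 ± 0.070), the chemokine receptor gene Ccr1l1 9.09-fold (3.18 ± 0.093) and the protease inhibitor gene Serpina3n 7.81-fold (2.97 ± 0.13). Xlr, Sgce and the respiratory chain gene Ndufa1 were higher by 3.95, 2.89 and 2.88. Ppbp, a chemokine of platelets, fell by 6.94 ± 0.12 (123-fold), Ngp, a granule protein of neutrophil precursors, fell by 6.47 ± 0.086, and Cpa3, a mast cell protease, fell by 6.31 ± 0.12. The class II gene H2-Aa fell by 6.19 ± 0.092. Further differences were -5.59 for the neutrophil gelatinase Mmp9, -5.37 for the IgE receptor subunit Ms4a2, -5.35 for the basophil protease Mcpt8 and -4.88 for the monocyte chemokine receptor Ccr2.

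P2ry12 and Sall1 were 5.60-fold and 3.62-fold higher in iPS-MG than in bm-Mac (2.49 ± 0.13 and 1.86 ± 0.12), while Cx3cr1 (0.01 ± 0.068) and Tmem119 (0.50 ± 0.086) did not pass. The Cx3cr1 values are not like for like, since iPS-MG carried gfp in place of 1 copy and bm-Mac did not. Of 29 microglia-enriched genes 9 rose and 1 fell, led by Fcrls (2.84) and Gpr34 (2.75), with Adgrg1 lowest at -1.65 (limma camera with Benjamini-Hochberg adjusted p = 9.57e-07). Cholesterol synthesis genes were higher in 9 of 16 cases, with Lss at 1.51 and Cyp51 at 1.39 (limma camera with Benjamini-Hochberg adjusted p = 2.57e-14). The bm-Mac samples carried transcripts of other blood lineages. All 14 granulocyte genes were lower in iPS-MG (median -3.67), from -1.14 for Camp to the value of Ngp, as were 9 of 15 mast cell and basophil genes and 6 of 13 haematopoietic progenitor genes, including Myb (-2.32) and Itga2b (-2.65) (limma camera with Benjamini-Hochberg adjusted p = 1.51e-21, 1.70e-10 and 8.77e-08).

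Lower in iPS-MG beside these lineage markers were 10 of 17 genes of the monocyte and bone marrow lineage (Chil3 -4.64), 7 of 11 of MHC class II presentation (H2-Ab1 -4.47, and Cd74 -4.04) and 11 of 21 of the peritoneal macrophage list (F5 -3.44, Selp -3.34). The same held for 7 of 24 dendritic cell genes (Clec10a -3.14, Kmo -2.85), 6 of 14 of alternative activation, and 10 of 28 of the interferon response (Oasl1 -1.76, Oas3 -1.73). Their adjusted p-values were 1.27e-07, 5.25e-11, 2.40e-06, 0.000167, 2.52e-07 and 4.31e-11 in that order (limma camera with Benjamini-Hochberg). Higher with the preset correlation only were neural progenitor genes (5 of 21, Fabp7 1.97; adjusted p = 0.0536 with an estimated correlation), astrocyte genes (3 of 11, Gfap 1.57; adjusted p = 0.14) and fibroblast genes (Postn alone, 2.09; adjusted p = 0.25), by limma camera with Benjamini-Hochberg. Adjusted over the list alone, no count against bm-Mac changed.

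Of 1018 genes called against bm-Mac, 434 were higher and 584 lower in iPS-MG. After centring 529 were higher and 505 lower, and the difference of Xist, -1.07 ± 0.059 in the deposited values, no longer passed at -0.98.

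Peritoneal macrophages differed from iPS-MG in genes of their own list and of the cell cycle. Adgrl2, an adhesion receptor, was 41.7-fold higher in iPS-MG (5.38 ± 0.094 log2 units, n = 3 each; limma with Benjamini-Hochberg adjusted p = 2.68e-24), as were Eif2s3y (4.97 ± 0.099) and the iron exporter gene Slc40a1 (4.74 ± 0.097). Prg4, the lubricating protein lubricin, fell by 6.69 ± 0.095, H2-Aa fell by 5.97 ± 0.092 and the lectin gene Cd209a fell by 5.82 ± 0.089. P2ry12 (1.64 ± 0.13), Sall1 (1.36 ± 0.12) and Aif1 (1.12 ± 0.15, but 0.94 and not passing after a second quantile normalization) were higher, and Itgam (-1.12 ± 0.098) and Arg1 (-4.00 ± 0.075) were lower. Cell cycle genes were higher in 23 of 27 cases (median 2.01; Ccna2 4.21, Bub1 4.13), and peritoneal macrophage genes were lower in 17 of 21 with Cd5l alone higher, at 4.53 (limma camera with Benjamini-Hochberg adjusted p = 1.17e-22 and 1.12e-14).

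Interferon response genes were higher in iPS-MG than in p-Mac in 12 of 28 cases (Ifit3 3.74). MHC class II presentation genes were lower in 9 of 11, dendritic cell genes lower in 6 and higher in 1 of 24 (Clec9a -2.52, Cd83 2.46), mast cell and basophil genes lower in 4 of 15, and granulocyte genes lower in 4 and higher in 1 of 14 (Mmp8 -3.19, Lcn2 1.59). Adjusted p-values were 2.74e-12, 2.04e-08, 0.00311, 0.000188 and 0.00394 in that order (limma camera with Benjamini-Hochberg). Lost with an estimated correlation were the calls of microglia-enriched genes (9 of 29 higher and 1 lower, adjusted p = 0.142), B cell genes (2 of 9 lower, Ms4a1 -2.65 and Cd79a -2.34; adjusted p = 0.113), lipid-associated genes (4 of 17 higher, adjusted p = 0.113), immediate early and stress genes (1 of 19 higher and 5 lower, adjusted p = 0.474) and cholesterol synthesis (0 of 16 called by limma and 13 at an unadjusted p under 0.05; adjusted p = 0.54), by limma camera with Benjamini-Hochberg. The cholesterol call also ended after a second quantile normalization (adjusted p = 0.449, limma camera with Benjamini-Hochberg). Counts adjusted over the list alone were the same. In all 1733 genes were called, 1139 higher and 594 lower in iPS-MG, and without the 2-fold minimum the direction turned, with 5092 higher and 8863 lower.

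Dendritic cells were the next reference for iPS-MG. Rnase2a, a secreted ribonuclease, fell by 7.79 ± 0.095 (221-fold) in iPS-MG, the kallikrein gene Klk1b11 fell by 7.57 ± 0.18 and Fbp1, an enzyme of gluconeogenesis, fell by 7.37 ± 0.094 (n = 3 each; limma with Benjamini-Hochberg adjusted p = 1.51e-27, 4.29e-22 and 4.14e-27). The membrane genes Ms4a6c and Ms4a6b and the lectin gene Clec4a1 were higher in iPS-MG by 6.86 ± 0.12, 5.90 ± 0.13 and 5.58 ± 0.15. Apoe (4.14 ± 0.061), Aif1 (3.97 ± 0.15), P2ry12 (3.14 ± 0.13), Sall1 (2.10 ± 0.12), Cx3cr1 (1.46 ± 0.068) and Csf1r (1.09 ± 0.080) were higher too, and H2-Aa (-4.95 ± 0.092) and Arg1 (-4.69 ± 0.075) were lower. Xist was 37.0-fold higher (5.21 ± 0.059), while Eif2s3y (-0.72 ± 0.099) did not pass.

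Alternative activation genes were lower in iPS-MG than in DC in 10 of 14 cases and higher in 2 (median -4.33; Chil3 -6.74, Mgl2 -5.75), dendritic cell genes lower in 10 and higher in 1 of 24 (Ccl17 -5.08, Irf4 -5.00) and MHC class II presentation genes lower in 7 and higher in 1 of 11 (limma camera with Benjamini-Hochberg adjusted p = 1.56e-09, 2.20e-06 and 2.79e-06). Cell cycle genes were higher in 20 of 27 cases (Kif23 3.01), cholesterol synthesis genes in 13 of 16 (Idi1 2.80), interferon response genes in 16 of 28 with 1 lower (Ifit3 5.30) and microglia-enriched genes in 11 of 29 (Gpr34 4.24). Complement and phagocytic receptors were higher in 10 and lower in 3 of 26 (C1qa 4.90), astrocyte genes higher in 5 of 11 (Gfap 1.64), and glycolysis and hypoxia genes lower in 7 of 17 (Vegfa -3.10). Adjusted p-values of these 7 lists, from cell cycle to hypoxia, were 5.39e-22, 4.66e-15, 5.48e-15, 2.73e-09, 1.60e-05, 0.000465 and 5.97e-07 (limma camera with Benjamini-Hochberg).

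With an estimated correlation the calls against DC were lost for neural progenitor genes (6 of 21 higher and 1 lower, adjusted p = 0.0539), fibroblast genes (2 of 16 higher, adjusted p = 0.0531), STAT5 targets and growth factor receptors (2 of 14 higher and 6 lower, Cish -3.97; adjusted p = 0.0608) and immediate early and stress genes (1 of 19 higher and 9 lower, adjusted p = 0.0609), by limma camera with Benjamini-Hochberg. They were also lost for granulocyte genes (3 of 14 lower, adjusted p = 0.112), purinergic receptors (4 of 10 higher and 2 lower, adjusted p = 0.2) and the oligodendrocyte lineage (Cnp alone of 12 higher, 1.74; adjusted p = 0.216), by limma camera with Benjamini-Hochberg. All counts against DC were the same adjusted over the list alone. Of 1503 called genes 777 were higher and 726 lower in iPS-MG, which turned to 3967 higher and 4465 lower without the 2-fold minimum.

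Neural stem cells served as a non-myeloid brain reference. C3ar1 was 200-fold higher in iPS-MG (7.65 ± 0.097 log2 units, n = 3 each; limma with Benjamini-Hochberg adjusted p = 4.32e-28), and Atp6v0d2 and Ms4a6c were higher by 7.40 ± 0.094 and 7.27 ± 0.12. The GABA receptor subunit gene Gabrg1 fell by 6.09 ± 0.066, the phosphatase gene Ptprz1 fell by 6.05 ± 0.11 and the imprinted gene Mest fell by 5.94 ± 0.13. Nestin, Nes, an intermediate filament of neural progenitors, was 3.99-fold lower, and Csf1r (5.45 ± 0.080) and Spi1 (5.66 ± 0.12) were higher. Pan-myeloid genes were higher in 28 of 29 cases (Cd53 7.16), interferon response genes in 28 of 28, and complement and phagocytic receptors in 20 of 26 with Tyro3 lower at -1.43 (limma camera with Benjamini-Hochberg adjusted p = 6.23e-23, 1.61e-17 and 9.49e-14). Neural progenitor genes were lower in 15 of 21 cases (median -1.84; Nfib -5.11; limma camera with Benjamini-Hochberg adjusted p = 4.38e-10).

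Further lists higher in iPS-MG than in NSC were the lipid-associated (15 of 17, Lpl 6.54), cytokine (19 of 31, Ccl3 6.68), monocyte (12 of 17), microglia-enriched (16 of 29 with 3 lower, Adgrg1 -3.68), purinergic (7 of 10), peritoneal macrophage (6 of 21 with 1 lower) and alternative activation lists (5 of 14). Adjusted p-values were 1.95e-12, 7.60e-10, 2.32e-06, 2.32e-06, 2.78e-06, 0.0031 and 0.0167 in that order (limma camera with Benjamini-Hochberg). Calls for the cell cycle (14 of 27 lower, Cenpf -2.14; adjusted p = 0.188 with an estimated correlation), STAT5 targets (7 of 14 higher, adjusted p = 0.0655), immediate early genes (11 of 19 higher, adjusted p = 0.149) and fibroblast genes (2 of 16 higher and 1 lower, adjusted p = 0.209) held only with the preset correlation (limma camera with Benjamini-Hochberg). No count against NSC changed when adjusted over the list alone. In all 3631 genes were called, 1984 higher and 1647 lower in iPS-MG, but 5343 higher and 6054 lower without the 2-fold minimum. After a second quantile normalization, with the 2-fold minimum, 1774 were higher and 1838 lower, so the direction with more genes depended on the scaling.

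**Figure D4:**
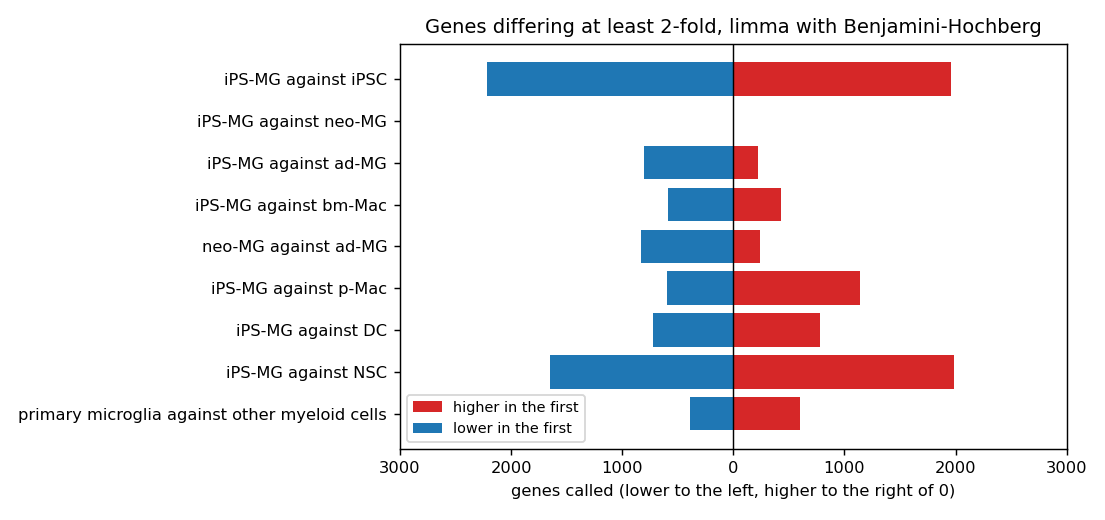
Number of genes called at an adjusted p under 0.05 and at least 2-fold by limma with Benjamini-Hochberg adjustment in each of the 9 comparisons, with bars to the right for genes higher and to the left for genes lower in the cell type named before "against". The bars run from 5 genes for iPS-MG against neo-MG to 4177 for iPS-MG against iPSC.

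Primary microglia of both ages were compared with the other myeloid cells in 15 arrays without the derived cells, to define genes on which iPS-MG were then placed. The p-values of single genes here measure the spread of arrays within cell types. They do not measure the spread between cell types, of which there were 2 against 3. Lox, which cross-links collagen, was 21.8-fold higher in microglia (4.44 ± 0.061 log2 units, n = 6 arrays against 9; limma with Benjamini-Hochberg adjusted p = 4.57e-20). The chemokine gene Ccl12 was higher by 3.95 ± 0.077, Ccr1l1 by 3.91 ± 0.065, the matrix gene Postn by 3.65 ± 0.048, Sgce by 3.64 ± 0.055 and Fcrls by 3.48 ± 0.041, and Xlr and Ddah1 by 3.58 and 3.50. H2-Aa fell by 5.81 ± 0.064 in microglia, and differences were -4.41 for Rgs18, -4.33 for Serpinb10, -4.24 for coagulation factor V (F5), -4.05 for Klk1b11, -3.88 for Gda, -3.86 for Arhgap15 and -3.83 for Arg1. P2ry12 (2.58 ± 0.080), Cx3cr1 (1.52 ± 0.046), Sall1 (1.41 ± 0.084), Apoe (1.45 ± 0.042), Aif1 (1.41 ± 0.073) and Tmem119 (1.02 ± 0.054) were higher in microglia. For Apoe and Aif1 DC lay lowest, at 9.66 and 6.36, while Apoe was at 13.94 in p-Mac, 13.83 in neo-MG and 13.73 in ad-MG, and Aif1 at 9.93 in bm-Mac and 9.60 in ad-MG. Tmem119 no longer passed without ad-MG replicate 3 (0.97). In fits chosen after the data were seen it lay at 0.90 without the bm-Mac arrays and 0.18 without the ad-MG arrays, where Cx3cr1 lay at 0.47, and neither passed.

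Of 29 microglia-enriched genes 13 were higher and 16 did not pass (median 0.81; Fcrls and Gpr34, the latter at 3.40, highest, and Upk1b lowest at -0.33 without passing; limma camera with Benjamini-Hochberg adjusted p = 3.10e-10). Fibroblast genes were higher in 10 of 16 cases (Dcn 2.68), and ad-MG stood apart, with a mean level of 10.18 against 8.16 in neo-MG, 7.91 in bm-Mac, 7.94 in p-Mac and 7.58 in DC. Lower in microglia were 12 of 14 granulocyte genes (Mmp8 -3.75), 9 of 14 of alternative activation with Mrc1 higher at 1.07, 13 of 21 peritoneal macrophage genes with Cd5l higher, 10 of 24 dendritic cell genes with 2 higher, 6 of 11 of MHC class II presentation, 5 of 15 mast cell and basophil genes (Cpa3 -3.46) and 10 of 17 of the monocyte lineage with Ms4a6c higher at 2.30. Adjusted p-values of these 8 lists, from fibroblast to monocyte, were 3.10e-10, 5.74e-09, 3.76e-08, 8.71e-07, 1.92e-05, 1.70e-05, 4.34e-07 and 0.000197 (limma camera with Benjamini-Hochberg). Single myeloid groups stood out in some lists. Granulocyte genes averaged 10.74 in bm-Mac, 7.77 in p-Mac and 7.52 in DC against 6.98 in neo-MG and 6.93 in ad-MG, and mast cell and basophil genes 8.39, 7.15 and 6.30 against 6.26 and 6.24. Alternative activation genes averaged 11.26 in DC and 9.24 in bm-Mac, and peritoneal macrophage genes 11.50 in p-Mac and 9.59 in bm-Mac.

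The other list calls between primary microglia and myeloid cells were lost with an estimated correlation. They were the cell cycle (13 of 27 higher, Ccna2 2.03, with mean levels of 10.30 in neo-MG, 9.73 in ad-MG, 10.35 in bm-Mac, 7.99 in p-Mac and 8.69 in DC; adjusted p = 0.0757), neural progenitor (4 of 21 higher and 1 lower, Nfib 2.60; adjusted p = 0.0757), astrocyte (2 of 11 higher, Gja1 1.83, but 0.37 and not passing without the ad-MG arrays; adjusted p = 0.109) and cholesterol synthesis lists (3 of 16 higher, Fdps 1.11; adjusted p = 0.109), by limma camera with Benjamini-Hochberg. For complement and phagocytic receptors (8 of 26 higher and 3 lower) adjusted p = 0.333, for B cells (2 of 9 lower) adjusted p = 0.315, and for haematopoietic progenitors (2 of 13 lower) adjusted p = 0.269, with an estimated correlation and limma camera with Benjamini-Hochberg. For STAT5 targets (3 of 14 lower, Cish -1.48) adjusted p = 0.356, and for sex-linked transcripts, where only Xist was higher (1.58), adjusted p = 0.0629, likewise. Adjusted over the list alone the counts were the same. T and NK cell, neuron and erythroid lists passed camera in no comparison, and between primary microglia and myeloid cells their adjusted p-values were 0.0673, 0.969 and 0.538 (limma camera with Benjamini-Hochberg). The sex-linked list passed against ad-MG, bm-Mac and p-Mac and for neo-MG against ad-MG, with adjusted p = 0.00492, 0.00157, 0.016 and 0.00649 and 3 of 4 transcripts higher each time, and it did not pass against DC or NSC (limma camera with Benjamini-Hochberg), although Eif2s3y was lower in iPS-MG than in NSC at -1.05 ± 0.099.

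Of 991 genes called, 602 were higher and 389 lower in primary microglia, and without the 2-fold minimum the direction turned, with 5059 higher and 8220 lower. In 514 of the 991 the 6 microglia arrays did not overlap the 9 others. Chance would give this for 0.04% of genes only if the arrays were independent of each other. Arrays of a cell type are alike, so that share does not apply here. The groups carried different Cx3cr1 alleles, so strain and cell type cannot be separated here or between iPS-MG and DC, NSC, bm-Mac or p-Mac. Sex-linked transcripts differed between groups too. In ad-MG, bm-Mac and p-Mac Xist was high and the Y genes low, in DC the reverse held, and neo-MG, iPS-MG and NSC carried both. Wherever these transcripts differ, sex cannot be separated from cell type or age.

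On the 514 genes without overlap, 0 marks the mean of the other myeloid groups and 1 that of primary microglia. iPS-MG lay at 0.94 ± 0.0055 (SD, n = 3), at 0.843 ± 0.032 over the 290 genes higher and at 0.975 ± 0.018 over the 224 genes lower in microglia, and 432 of the 514 genes (84%) put them nearer to microglia. iPSC (0.979 ± 0.0075) and NSC (1.04 ± 0.0080), which are no microglia, scored alike, since genes low in microglia were low in them too (1.11 ± 0.0079 and 1.14 ± 0.016). On the genes higher in microglia they lay at 0.638 ± 0.025 and 0.523 ± 0.028. The score therefore does not single out microglia. Placed on axes set without them, each with its own genes, neo-MG lay at 0.24 ± 0.0052, ad-MG at 0.688 ± 0.021, bm-Mac at 0.396 ± 0.016, p-Mac at 0.263 ± 0.032 and DC at 0.539 ± 0.0034. For neo-MG the microglia end was ad-MG alone, on 1102 genes. There neo-MG lay at 0.112 ± 0.0081 over the 791 genes higher in ad-MG, but at 0.876 ± 0.0094 over the 311 genes lower in ad-MG. With the microglia end set by ad-MG alone, an alternative chosen after the data were seen, iPS-MG lay at 0.25, so the value depended on neo-MG being among the references.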

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

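Fits without the arrays or with the reference ends named below as added, and the list tests after another scaling, were chosen after the data were seen. Counts of called genes stayed within 1.5 times under every alternative but 1. Without the 2-fold minimum they were 12146 for iPS-MG against iPSC, 40 against neo-MG, 7957 against ad-MG, 8438 against bm-Mac, 13955 against p-Mac, 8432 against DC and 11397 against NSC, 8338 for neo-MG against ad-MG and 13279 for primary microglia against other myeloid cells, by construction, since smaller differences then count. With each replicate left out in turn the counts ran from 4168 to 4195, 5 to 6, 1021 to 1067, 987 to 1050, 1695 to 1769, 1507 to 1519, 3613 to 3676, 1045 to 1098 and 976 to 1004 in the same order. The position of iPS-MG, 0.94 in the report, was 0.921 with genes of at least 4-fold, 0.834 with the microglia-enriched list, 0.851 as a ratio of sums, 0.913 after centring, 0.92 after quantile normalization, and, in added settings, 0.25 with the ad-MG end alone and 0.993 without bm-Mac; the cause was not tested. The highest similarity was 0.9965 over the 1000 genes of highest variance and 0.997 without dim genes, and r turned to -0.08273 with iPSC and -0.09914 with NSC over those 1000 genes, since genes alike in all groups were left out. Of the 279 list tests 126 passed, 73 with an estimated correlation and 212 with fry, which asks another question. Of 395 gene values, those named in the texts included, 276 were called, 269 under every alternative, and 0 reversed. The primary microglia count was 1148 without bm-Mac, sharing 869 genes with the 991 in the report, and 1026 without ad-MG, sharing 670. In NSC the share of higher genes moved from 54.6% to 49.1% after quantile normalization.

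The replicate block left all counts as they were, with 5 genes for iPS-MG against neo-MG and 991 for primary microglia, and all 279 list calls. Replicate numbers did not pair the arrays: of 42 pairs with the same number 10 correlated over 0.1, no comparison had all its pairs over 0.1, r ran from -0.226 to 0.251, and in 16 of the 42 no other number gave a higher r. Array signals include background, so the fold of a gene near the floor of the arrays is not a fold of its transcript, and whether such a gene was expressed was not tested.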

Other observations

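All tests of explanations below, and the counts of other splits of the arrays, were chosen after the results they bear on were seen, and so were the genes named here and in the paragraph that follows. At least 2-fold above the highest other group mean stood 673 genes in iPSC, 505 in NSC, 178 in ad-MG, 141 in DC, 115 in bm-Mac and 89 in p-Mac. The count was 0 for iPS-MG and 0 for neo-MG, a count of means without a test, while 19 genes lay that far above the other 6 groups in both together. Among these were the complement gene C2 (10.02 in iPS-MG, 10.04 in neo-MG and 8.13 in ad-MG), Cnrip1 (12.03, 11.99 and 10.58), Adamts1 (11.95, 12.02 and 10.57) and Ttr, the thyroxine carrier (9.72, 9.68 and 8.28). Dendritic cells carried the retinol carrier gene Rbp4 at 13.21 log2 units, the chitinase-like gene Chil4 at 10.19 and the fatty acid hydroxylase gene Cyp4a12a at 11.73, which lay at 7.72 (ad-MG), 5.28 (bm-Mac) and 5.88 (p-Mac) in the highest other group.

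The ad-MG samples held prolactin (Prl), a pituitary hormone, at 11.11 ± 0.32 log2 units (SD, n = 3), where the other groups lay between 5.85 and 6.44, and the source of this signal was not tested. Growth hormone (Gh) was at 7.50 ± 0.092 in ad-MG and between 7.40 and 7.93 elsewhere, and Pomc at 7.46 ± 0.036 and between 7.34 and 7.75. The matrix genes Mgp and Lama2 were at 12.50 and 10.09 in ad-MG and at 8.62 and 6.83 in neo-MG, and Cst7, a protease inhibitor of activated microglia, at 12.86 and 9.67. Cxcl13, a chemokine for B cells, was at 13.38 in p-Mac and 9.92 in the next group, ad-MG, beside the B cell gene Ms4a1 at 8.34 in p-Mac and 6.08 in bm-Mac. The glutamate receptor gene Gria2 (11.41) and the matrix gene Bcan (12.71) stood out in NSC.

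iPS-MG carried Xist and Y chromosome transcripts together, at the levels of neo-MG. NSC carried both together too, above every iPS-MG array. NSC arrays lay at 12.921 to 12.98 for Xist, 11.074 to 11.2 for Eif2s3y, 9.225 to 9.456 for Kdm5d and 10.343 to 10.451 for Uty. On the linear scale, the Y genes Eif2s3y, Kdm5d and Uty in iPSC lay at 4.86%, -0.261% and 22.5% of the way from ad-MG, bm-Mac and p-Mac to DC, against 60%, 49.8% and 70.3% in iPS-MG. Uty in iPSC thus lay above ad-MG, bm-Mac and p-Mac but well below iPS-MG. The tables argue against cells of 1 sex alone, since Xist lay 5.21 log2 units above DC, and the Y genes at least 2.044 above ad-MG, bm-Mac and p-Mac. They also argue against 1 RNA preparation handled alike on all 6 arrays, since 40 genes differed between iPS-MG and neo-MG at an adjusted p under 0.05 by limma with Benjamini-Hochberg and at most 1 in another split of these arrays. The split cannot tell different RNA from arrays labelled or hybridised in separate sets by group. A candidate explanation that stays open is that mixed-sex cells like neo-MG gave most of the RNA, since each sex transcript, on the linear scale and above the mean of the groups low in it, reached at least 85.8% of its value in neo-MG, but that value restates the pattern and decides nothing, and iPSC lines of both sexes, or a line other than the one on the iPSC arrays, were not tested.

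Fibroblast and vessel transcripts were higher in ad-MG than in neo-MG, with 13 of 16 fibroblast genes called. The neuron, astrocyte and oligodendrocyte lists had medians of at most 0.184 in ad-MG minus neo-MG, against 2.362 for the fibroblast list. These values argue against a share of microglia lost to those neural cells as the whole cause. They cannot speak to a share lost to stromal cells. The pan-myeloid list averaged 12.32 ± 0.0311 in ad-MG and 12.325 ± 0.0153 in neo-MG (SD, n = 3 each). No loss of myeloid signal showed there, but a small stromal share or a change of level per cell could go unseen. The tables also argue against scaling between arrays as the whole cause, since 12 of the 13 genes were still called after centring. Stromal cells in the ad-MG samples could account for the pattern, but the median of 2.362 is part of it, and the vessel list lost its call with an estimated correlation (limma camera with Benjamini-Hochberg adjusted p = 0.0929). The age and the sex of the mice and expression by the microglia stay open and were not tested.

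Of the 40 genes higher in iPS-MG than in neo-MG at an adjusted p under 0.05, 25 (62.5%) were also called higher in DC than in bm-Mac and p-Mac, where 1.72 were expected from the 811 such genes of 18820, and 19 (47.5%) in ad-MG, where 2.18 were expected. These overlaps share genes, with 13 of the 40 in both and 31 in either. The expected counts treat all genes alike, whereas the 40 had to vary detectably, so they may understate chance. The tables argue against DC RNA in the iPS-MG samples as the whole cause: the share needed by the genes of the pattern (median 4.43% over 30 genes) would have raised the 52 genes most enriched in DC by a median of 1.16, and 0.134 was found. RNA of ad-MG would have needed a share of 8.79% and a rise of 1.36 over 12 genes, and 0.163 was found. Growth factors in the medium may be involved, but the list of STAT5 targets and growth factor receptors passed with the preset correlation and not with an estimated one (limma camera with Benjamini-Hochberg adjusted p = 0.000364 and 0.0802), and the labels do not say which cells received the factors. A smaller share of either RNA, and both together, stay open. Overlap of the 40 genes with genes high in iPSC was not tested, so a part played by such genes stays open. Most of the 40 had a higher mean in iPSC than in neo-MG. Examples chosen after the values were seen are Uck2 (12.82 against 8.33), Car4 (11.2 against 7.17) and Socs2 (11.59 against 7.71). Others were lower in iPSC, such as F13a1 (6.99 against 8.82) and Ccr1 (5.04 against 7.74). Of the 5 called genes, Timp3, Fn1 and Ccn3 were higher in iPSC than in neo-MG (11.23 against 8.56, 13.37 against 10.79 and 8.49 against 7.63). Car6 and Arg1 were close (6.91 against 6.82 and 6.97 against 7.19).

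Other splits of the arrays were counted for each comparison. With 3 arrays against 3 there are 10 splits, which are too few for a share under 0.05. Every split but the real one mixes both cell types in each group. A large real difference then counts as spread, so few or no calls there were fixed in advance and do not test chance. Of the 10 splits only 1, the real one, gave as many called genes in each of the 8 comparisons of 2 cell types, with 4177 genes for iPSC, 5 for neo-MG, 1031 for ad-MG, 1018 for bm-Mac, 1733 for p-Mac, 1503 for DC and 3631 for NSC against iPS-MG and 1075 between neo-MG and ad-MG, and the highest other split gave 0 by limma. For primary microglia against other myeloid cells, arrays of a cell type are alike, so whole cell types were divided, 2 against 3. Of these 10 splits, again too few for a share under 0.05, 1, the real one, gave as many genes (759 in a fit of 2 groups), and the highest other, bm-Mac and p-Mac against the rest, gave 691. The 100 splits of single arrays counted first gave at most 251 beside the real one, but they break up cell types and so do not test this.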
